A study of Mus musculus with 4 samples.

How the data were processed

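Total RNA of E14 mouse embryonic stem cells was measured on 4 one-colour Affymetrix gene arrays, 2 of cells given esiRNA against Ogt and 2 of cells given esiRNA against GFP, each taken 48 h after transfection. Per the labels' protocols, 150 ng of RNA was turned into biotin-labelled cDNA with whole-transcript kits. The deposited values are on the log2 scale, and per the submitters' processing notes they were made with RMA, which corrects background, equalises the arrays' distributions and summarises the probes of a probe set. The authors' deposited table of the comparison holds a log2 fold change and a p-value for each probe set, and per the submitters' processing notes limma was used. No versions of RMA or limma are stated in the labels. The array type, its annotation release and the genome build are not given in the sources used here, so no coordinates are printed. Scan dates and slides are not given in the sources used here, so batches could not be looked for. The number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

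The table lists 34760 probe sets, of which 23346 name 1 gene symbol (20723 symbols, 1583 with more than 1 probe set), 11414 name none and 0 name several. A further property of the table is that 6568 probe sets have a dash in place of an accession, and the file does not say what they are. Current symbols were looked up by accession in a RefSeq gene table of assembly GRCm38.p6, used for names alone. It held the accession of 21780 probe sets with a symbol, and 19802 of them carry the same symbol today. Genes are named as in the file.

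The 2 groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values of all probe sets, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The fit has 2 residual degrees of freedom, and 4.38 in all after moderation. Run this way, it gave the p-values of the authors' deposited table to within 4.84e-08 and its log2 fold changes to within 4.55e-08. In the authors' deposited table Ogt has a p of 0.00057 and a log2 fold change of -1.54. The expression values given there are identical to those of the value table.

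Before the data were examined, 27 gene lists were fixed (669 genes, each counted once). They cover O-GlcNAc cycling and the hexosamine pathway, DNA methylation and TET, Ogt partner complexes, Polycomb complexes, naive pluripotency, primed epiblast, primitive streak and mesoderm, endoderm, trophectoderm, neuroectoderm, the 2-cell-like state, germline genes, imprinted genes, Hox genes, interferon response, p53 targets, the ATF4 response, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, G1/S, G2/M, LIF/STAT3 and ERK targets, Wnt, Nodal and BMP targets, ribosomal proteins, canonical histones and fibroblast markers. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean), adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it, and neither was tried on simulated data. Each member was also adjusted over its list alone, without a further correction for the number of lists.

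The genes named in the text follow a rule that was also fixed before the data were examined. It takes Ogt, then up to 13 genes per direction that pass and whose silenced arrays lie outside the control range. If fewer than 10 pass, the direction is filled to 10 by the smallest p. It adds up to 4 members with the smallest p from each list, and Tet1, Tet2, Pou5f1, Nanog and Sox2 whatever their values. Some list members taken by the rule are not reported here.

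The test was tried on simulated data with 34760 probe sets and 200 changed genes. At a log2 change of 1 it called 0 of 50 genes, at 1.5 it called 7, at 2 it called 22 and at 3 it called 34, and it called 0 of the unchanged probe sets, of which 5.61% had an unadjusted p under 0.05. In a simulated list test, the 1 shifted list was found (camera, adjusted p = 1.96e-12) and 0 of the other 26 lists were called. The simulated noise was independent between genes. In the data the estimated correlation was 0.928 in the cholesterol list and 0.567 in the ribosomal list. The simulation therefore cannot show how often lists whose members move together are falsely called at the preset correlation.

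The alternatives tried were centring each array on its median, quantile normalization, leaving out probe sets below the median level, leaving out probe sets that do not name 1 gene, a variance trend with level, a robust variance prior, the replicate number as a block, other thresholds, the mean of a gene's probe sets, the other list tests, and leaving out each array in turn.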

Results

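The data were 4 one-colour expression arrays of E14 cells, a mouse embryonic stem cell line. The cells were kept in 15% serum with LIF, the cytokine that holds such cells in self-renewal. They were transfected with esiRNA, a pool of short interfering RNAs made by enzymatic digestion of a long transcript. In 2 samples the pool targeted Ogt, and in 2 control samples it targeted GFP, which these cells are not said to carry. Total RNA was taken 48 h after transfection. Each array gave a log2 expression value for 34760 probe sets. The array medians were 6.40 and 6.46 in the control samples and 6.41 and 6.43 in the silenced samples. Across probe sets, which are not independent replicates, Pearson's r was 0.989 between the control arrays and 0.986 between the silenced arrays. Between arrays of different groups it was 0.991 and 0.990 for those of the same replicate number, above both replicate pairs, and 0.984 in both cases for those of unlike number, below both replicate pairs.

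The series title sets the arrays beside the question of how TET proteins bring Ogt to chromatin, and the comparison made here asks which transcripts differ when Ogt is silenced. Ogt encodes the enzyme that adds O-linked N-acetylglucosamine (O-GlcNAc) to proteins. Its transcript was 2.91-fold lower in the silenced samples. The level was 11.45 ± 0.09 (SD, n = 2) in the control samples and 9.91 ± 0.26 (SD, n = 2) in the silenced samples. Single arrays read 11.51 and 11.38 in the control group against 9.73 and 10.09 in the silenced group. The log2 change was -1.54 (SE 0.17). Both silenced arrays lay below both control arrays, and the exact two-sided permutation test gave p = 0.333, the smallest p that 2 arrays against 2 allow. In limma's moderated test the unadjusted p was 0.00057 and the adjusted p over all probe sets was 0.674. Mgea5, now named Oga, encodes the enzyme that removes the same sugar, and its transcript was 2.89-fold lower, with a log2 change of -1.53 (SE 0.16).

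**Figure D1:**
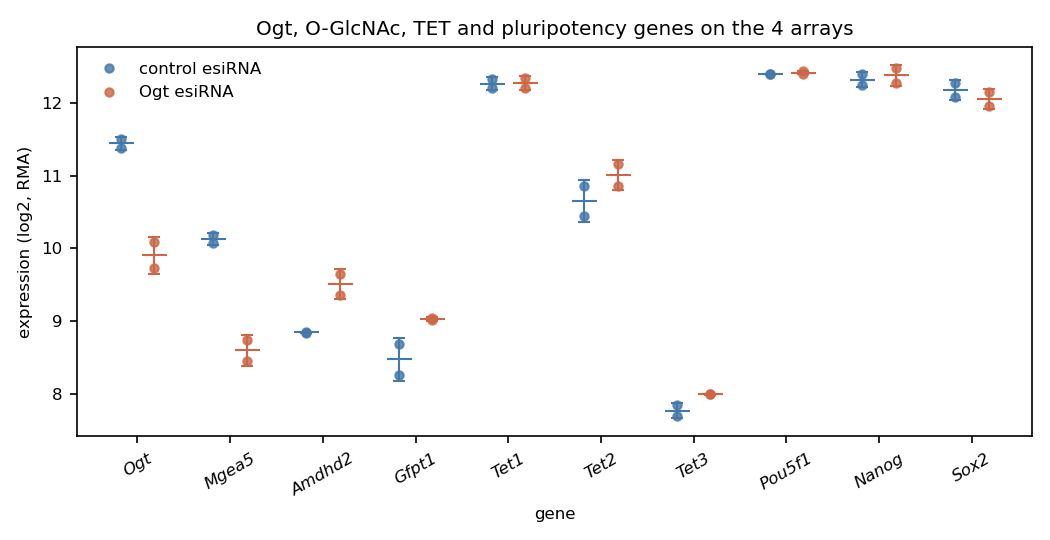
Log2 expression (RMA values) of 10 genes in each of the 4 arrays, with the group mean (horizontal mark) and SD (bar) of the control and the Ogt-silenced samples. Ogt moved from a mean of 11.45 to 9.91 and Mgea5 from 10.13 to 8.60, while Pou5f1 stood at 12.40 and 12.42.

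No probe set passed an adjusted p of 0.05 in limma (0 of 34760), Ogt included. The smallest adjusted p was 0.674. At an unadjusted p under 0.05 there were 2565 probe sets, 1426 higher and 1139 lower in the silenced samples, where chance alone gives 1738. Setting the arrays of replicate 1 against those of replicate 2 gave more, 4158, and the crossed split of the same arrays gave 514. Each replicate number occurs once per group, so a difference between numbers adds to the spread of the group fit. With the replicate number as a block, a pairing the labels do not state, the count was 5279. The splits cannot decide where the excess over chance comes from, and it is not shown to come from silencing. Of the 2565, 827 had no accession in the file, 585 of them higher and 242 lower. With 1 probe set per gene, 1256 of 20723 gene symbols stood at that level, 704 higher and 552 lower, against 1036 by chance. That is 6.06% of the symbols, where the replicate split gave 11.6% and the crossed split 0.188%. Of these, 367 also differed by 1.5-fold or more. The groups did not overlap for 39.1% of probe sets, and chance gives 33.3% for 2 arrays against 2.

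Since fewer than 10 genes passed in either direction, the 10 genes with the smallest p per direction are given, and none of them passes the test over all genes. Rnf17, a Tudor domain gene of germ cells, was 3.49-fold lower, with a log2 change of -1.80 (SE 0.14). The uncharacterised 1700001L05Rik was 3.23-fold lower and Nxt2, a factor of nuclear RNA export, 3.08-fold lower. Beside Ogt and Mgea5, the others were Pnma5 (2.85-fold lower), the transcriptional repressor gene Zhx1 (2.67-fold), Fam111a (2.64-fold), the monoamine transporter gene Slc29a4 (2.31-fold) and Rundc3b (2.16-fold). Among the higher values, Enpp2, which encodes the lysophospholipase autotaxin, was 2.44-fold higher, with a log2 change of 1.28 (SE 0.16). The actin-bundling gene Pls1 was 2.10-fold higher, the guidance receptor gene Robo1 2.05-fold and Ica1 2.01-fold. Zcwpw1 was 1.97-fold higher, Rnf165 1.90-fold, the synaptonemal complex gene Sycp1 1.87-fold and the repressor gene Bcl6 1.77-fold. Smarca2, an ATPase gene of the SWI/SNF remodelling complex, was 1.73-fold higher and Odz3, now named Tenm3, 1.64-fold. For all 20 genes the silenced arrays lay outside the range of the control arrays, and each gene had a single probe set. Picking genes by the smallest p makes such a gap likely, and 39.1% of all probe sets showed one.

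**Figure D2:**
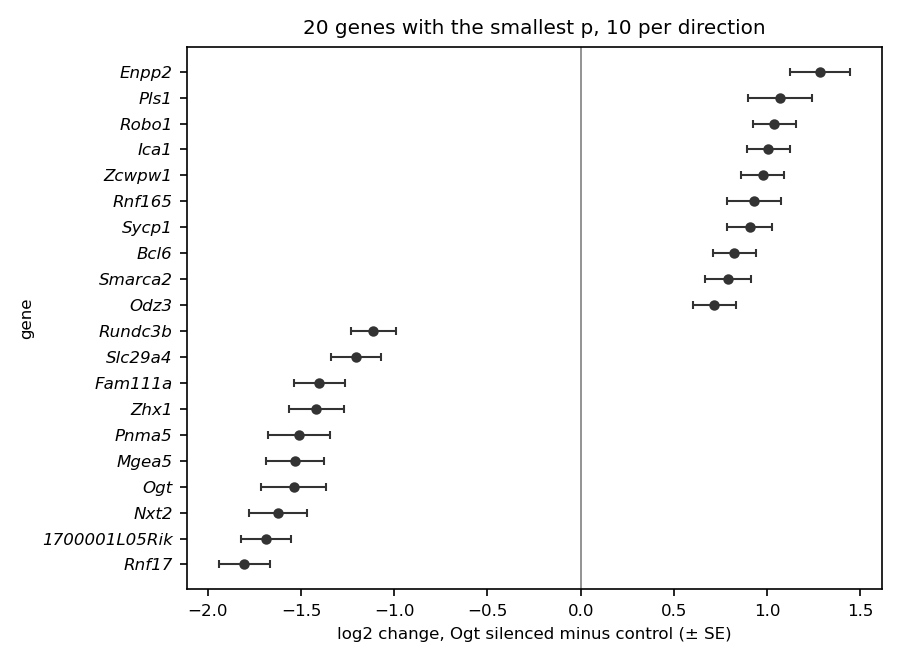
Log2 change (silenced minus control) with its SE for the 20 genes with the smallest p, 10 per direction. The lower genes range from -1.80 (Rnf17) to -1.11 (Rundc3b) and the higher genes from 0.72 (Odz3) to 1.28 (Enpp2).

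The genes were grouped in 27 lists, and each list was also adjusted over the list alone. In the list of O-GlcNAc cycling and the hexosamine pathway, which makes the sugar donor of Ogt, 3 of 12 measured genes passed when adjusted over the list alone and 0 over all genes. Ogt and Mgea5 fell (both adjusted p = 0.0034 over the list). Amdhd2, a deacetylase gene of the same sugar pathway, rose 1.58-fold, with a log2 change of 0.66 (SE 0.15, adjusted p = 0.039 over the list). Gfpt1, which encodes an enzyme of the pathway's entry step, had a log2 change of 0.55 (SE 0.18) and did not pass. Gfpt2, which encodes the other form, went the opposite way, at -0.14 (SE 0.18). With 5 members higher and 7 lower, the list as a whole did not differ from other genes (camera, adjusted p = 0.769). The call of Amdhd2 was lost without control 1, without control 2 or without silenced 2, which left 2 genes passing, Ogt and Mgea5.

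None of the 19 genes of DNA methylation and TET passed (12 higher, 7 lower, median log2 change 0.06, camera adjusted p = 0.504). The TET genes encode the dioxygenases that oxidise methylcytosine. Tet1 had a log2 change of 0.01 (95% confidence interval -0.33 to 0.36), Tet2 of 0.36 (-0.20 to 0.91) and Tet3 of 0.23 (SE 0.12). Mbd1, a methyl-CpG binding gene, had 0.72 (SE 0.37) and Gadd45a -0.30 (SE 0.14). None of the 23 Ogt partner genes, such as the Hcfc1, Sin3a and Set1 complexes, passed (12 higher, 11 lower, median 0.01, adjusted p = 0.512), and Wdr5 stood at 0.29 (SE 0.12). Of 24 Polycomb genes, 16 were higher and 8 lower, with 0 passing (median 0.05, adjusted p = 0.504). Ezh2, the methyltransferase of the complex, stood at -0.35 (SE 0.15).

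The genes of the pluripotent state did not pass either. Pou5f1 had a log2 change of 0.01 (95% confidence interval -0.29 to 0.32), Nanog of 0.06 (-0.33 to 0.44) and Sox2 of -0.12 (-0.51 to 0.27). The intervals of these 3 genes do not reach a 2-fold change, but they rest on 2 arrays per group, whose spread may be technical. Of 27 naive pluripotency genes, 18 were higher and 9 lower (median 0.03, adjusted p = 0.603). Esrrb stood at 0.31 (SE 0.11) and Tcl1 at -0.52 (SE 0.21). Of 15 primed epiblast genes, 6 were higher and 9 lower (median -0.01, adjusted p = 0.437), with Sox3 at -0.38 (SE 0.12). The 20 targets of LIF/STAT3 and ERK had 11 higher and 9 lower, with a median of 0.03, a mean of -0.11 and a test that pointed lower (adjusted p = 0.504). Etv4, a target of ERK, stood at -0.76 (SE 0.13) and missed the threshold over the list (adjusted p = 0.058).

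Of 21 targets of Wnt, Nodal and BMP signals, 7 were higher and 14 lower, with a median log2 change of -0.16 (camera adjusted p = 0.036). That call was lost with an estimated correlation (adjusted p = 0.774), in fry (0.828), after quantile normalization (0.0593), among probe sets above the median level (0.111), without control 2 (0.263) and without silenced 1 (0.400). The Nodal targets Lefty1 and Lefty2, which encode inhibitors of Nodal, had log2 changes of -1.36 (SE 0.42) and -1.22 (SE 0.47), and Nkd1, a Wnt target, of -0.34 (SE 0.12). No single member passed over the list alone.

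Markers of differentiated cells were mixed. Of 26 primitive streak and mesoderm genes, 7 were higher and 19 lower (median -0.12, adjusted p = 0.073), with Fgf8 at -0.22 (SE 0.12). The endoderm list had 14 higher and 11 lower of 25 (median 0.05, adjusted p = 0.693), with the basement membrane genes Col4a2 at 0.40 (SE 0.12) and Lama1 at 0.34 (SE 0.12), and Amn at -0.40 (SE 0.13). Trophectoderm markers had 11 higher and 7 lower of 18 (median 0.02, adjusted p = 0.519), with Cited1 at 0.64 (SE 0.18) and Esx1 at 0.53 (SE 0.18). Neuroectoderm markers had 8 higher and 11 lower of 19 (median -0.05, adjusted p = 0.512), with Sox11 at -0.35 (SE 0.13). Of 39 Hox genes, 13 were higher and 26 lower (median -0.07, adjusted p = 0.276). Fibroblast markers, which feeder cells would bring, had 9 higher and 17 lower of 26 (median -0.06, adjusted p = 0.328). Vim stood at -0.49 (SE 0.14) and Fn1 at 0.44 (SE 0.15), both abundant transcripts, and Fbn1 at 0.54 (SE 0.15), where only 1 of its 2 probe sets went that way. No gene of these 6 lists passed over its list alone.

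The list of germline genes, drawn up as genes silenced by DNA methylation, had the most single-gene differences of the 27 lists. Of 28 measured, 11 stood at an unadjusted p under 0.05, 4 higher and 7 lower, and 5 passed when adjusted over the list alone. DNA methylation was not measured, and not all members were silent in the control samples. There the mean level was 9.08 for Zcwpw1 and 9.14 for Sycp3, but 5.37 for Sycp1. Zcwpw1, a histone methylation reader of meiotic cells, rose 1.97-fold (adjusted p = 0.017 over the list) and Sycp1 rose 1.87-fold (adjusted p = 0.017). Sycp3, another gene of the synaptonemal complex, fell 2.73-fold (adjusted p = 0.026). The piRNA pathway gene Piwil2 fell 1.58-fold (adjusted p = 0.026) and the dimly expressed Tex11 fell 1.72-fold (adjusted p = 0.036). The list did not shift as a whole. Its median log2 change was 0.03 and its mean 0.01, while the test pointed lower (camera adjusted p = 0.687). Without control 1, without control 2 or without silenced 2, 0 members passed over the list. Without silenced 1, 7 passed, 4 of them among these 5, and the call of Piwil2 was lost. Fits without 1 array have fewer residual degrees of freedom, so a lost call does not show that the differences are gone. In each of them the members still stood at an unadjusted p under 0.05 more often than gene symbols as a whole. The filter on level removes Sycp1 and Tex11 before the test, and of the members it keeps 6 passed, 3 of them among these 5. With probe sets naming 1 gene 9 members passed, and with the replicate block 12, each time with these 5 among them.

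Of 31 imprinted genes, 14 were higher and 17 lower (median -0.07, adjusted p = 0.314), and none passed over the list alone. The list passed as lower without silenced 2 (adjusted p = 0.0192) and pointed higher without silenced 1 (0.975), both at the preset correlation. With all arrays its adjusted p was 0.774 with an estimated correlation. The noncoding transcript Mirg had a log2 change of -0.77 (SE 0.14) and the growth inhibitor gene Cdkn1c of -0.57 (SE 0.12), while Zim1 stood at 0.59 (SE 0.14) and Nnat at 0.52 (SE 0.16). The list of the 2-cell-like state, genes of the early embryo that rare stem cells express, had 3 higher and 14 lower of 17 measured (median -0.34, adjusted p = 0.276). Leaving out 1 array unbalances the replicate numbers between the groups. The list followed that imbalance in direction and call. It passed as lower without control 1 (adjusted p = 4.73e-08) and without silenced 2 (3.91e-05), and pointed higher without control 2 (0.0983) and without silenced 1 (0.400). Those values use the preset correlation, and with all arrays the adjusted p was 0.787 with an estimated correlation and 0.859 in fry. With the replicate number as a block, a pairing the labels do not state, the list passed as lower (camera adjusted p = 2.97e-05, preset correlation). Tdpoz5 stood at -0.81 (SE 0.64). It read 5.38 and 6.79 in controls 1 and 2, and 4.66 and 5.89 in silenced 1 and 2.

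Of 24 cholesterol synthesis genes measured, 20 were lower and 4 higher, with a median log2 change of -0.20 (camera adjusted p = 0.00057). That call was lost with an estimated correlation (adjusted p = 0.774), in fry (0.828), without control 1 (0.166) and without silenced 2 (0.578). Hsd17b7, an enzyme of the late pathway, fell 2.77-fold and was the one member to pass over the list alone (adjusted p = 0.049). Stard4, which carries cholesterol, stood at -1.21 (SE 0.46). Hsd17b7 no longer passed over the list after quantile normalization, with a variance trend, with a robust prior, without either control array or without silenced 2.

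The interferon response list was lower in 27 of 34 genes, with a median log2 change of -0.13 (camera adjusted p = 0.029). The adjusted p was 0.774 with an estimated correlation, 0.629 in fry, 0.234 without control 2 and 0.164 without silenced 1. Parp9 stood at -0.54 (SE 0.14), Parp14 at -0.49 (SE 0.16) and the dim Ifit2 at -0.48 (SE 0.14). None passed over the list alone. The p53 targets had 11 higher and 14 lower of 25 (median -0.02, adjusted p = 0.603). The ATF4 amino acid response had 12 higher and 19 lower of 31 (median -0.04, adjusted p = 0.276, and 0.00690 without silenced 1, both at the preset correlation, and 0.774 with an estimated correlation and all arrays), with the serine synthesis genes Psat1 at -1.17 (SE 0.35) and Phgdh at -0.44 (SE 0.15). The unfolded protein response list had 10 higher and 10 lower (median 0.04, adjusted p = 0.519), with Hspa5 at 0.28 (SE 0.12). Glycolysis and hypoxia genes had 14 higher and 10 lower of 24 (median 0.02, adjusted p = 0.519), with Pfkm at 0.50 (SE 0.14).

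All 53 ribosomal protein genes were lower, with a median log2 change of -0.16 (camera adjusted p = 3.8e-06), and none stood at an unadjusted p under 0.05. The adjusted p was 0.774 with an estimated correlation, 0.828 in fry and 0.064 without silenced 2. Setting the arrays of replicate 1 against those of replicate 2 moved 47 of the 53 genes one way, with a median of -0.17. The crossed split moved 31 of the 53 one way, with a median of 0.014. Rps24 was at -0.42 (SE 0.21) and Rpl13 at -0.40 (SE 0.20). Canonical histone genes were lower in 30 of 34 measured (median -0.12, camera adjusted p = 0.00046). Their adjusted p was 0.774 with an estimated correlation, 0.726 in fry and 0.075 without silenced 2. Hist1h2aa, a testis-type histone, stood at -1.08 (SE 0.29) and Hist1h4c at -0.45 (SE 0.15). Among G1/S genes 12 were higher and 13 lower of 25 (median -0.00, adjusted p = 0.693), with the cyclin gene Ccne1 at -0.82 (SE 0.23). Among G2/M genes 5 were higher and 18 lower of 23 (median -0.05, adjusted p = 0.288), with Top2a at -0.32 (SE 0.17). No member of these 4 lists passed over its list alone.

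**Figure D3:**
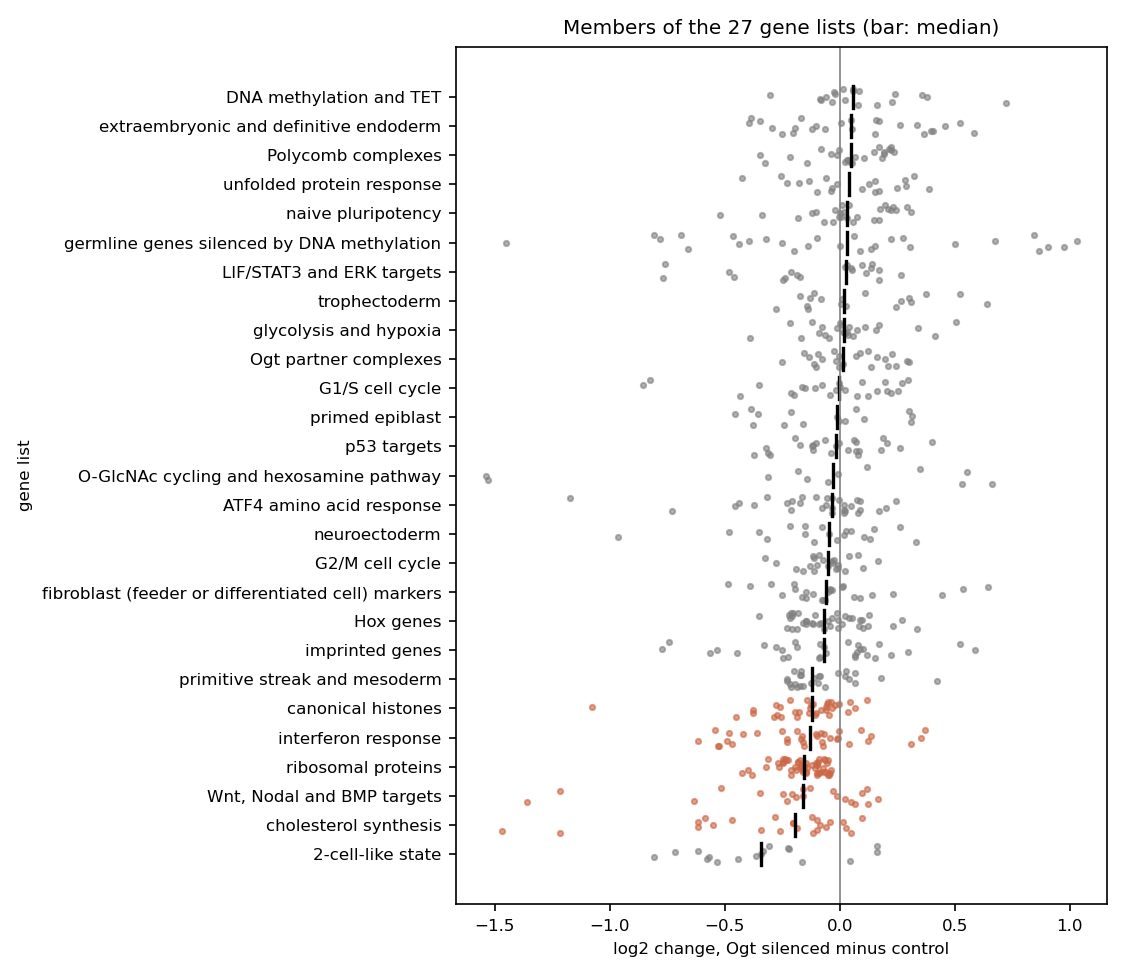
Log2 change (silenced minus control) of each measured member of the 27 lists (points), with the list median (bar), ordered by median. Coloured points mark the 5 lists with a camera adjusted p under 0.05, whose medians lie between -0.20 (cholesterol synthesis) and -0.12 (canonical histones).

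Of the 27 lists, 5 passed in camera with the preset correlation, and 0 passed with an estimated correlation or in fry. Camera with an estimated correlation tests on the 2 residual degrees of freedom, which leaves it little power. For the interferon list the estimated correlation was -0.023, below the preset 0.01, yet the unadjusted camera p rose from 0.0043 to 0.081. Neither that setting nor fry was tried on simulated lists. Their 0 calls therefore do not show that the 5 calls were false, and the 5 are not shown to hold either. With 2 arrays per group, simulated changes of 1 log2 unit were called in 0 of 50 genes and changes of 3 units in 34 of 50, so a gene that does not pass here is not shown to be unaltered.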

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

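The alternatives without the accession-less probe sets, and those that join the replicate block with probe sets naming 1 gene (alone or with a variance trend), were chosen after seeing the data. The cause of the shifts below was not tested, except that settings without 1 array have fewer samples and assume that the lone array of a group varies like the other group. The log2 change of Ogt was between -1.55 and -1.53 in the settings that keep all 4 arrays, and between -1.72 (without silenced 2) and -1.36 (without silenced 1) without 1 array. The count of 0 passing probe sets held in limma under median centring, quantile normalization, both filters, the variance trend, the robust prior, an adjusted p of 0.1 and without any 1 array. Outside the settings without 1 array, 1180 values of named genes kept their direction and side of the threshold and 82 passed, and for lists the figures were 201 kept, 12 no longer passing, 1 now passing and 2 turned. Without 1 array, 504 named-gene values kept and 8 turned, while 79 list values kept, 17 turned, 8 no longer passed and 4 now passed. A robust prior for camera (the tool has none) and the other deposited table (its values are identical) were not run, and the filter on annotation was not run for camera, whose input already holds only probe sets naming 1 gene.

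The labels state no pairing, and 2 pairs share only a number. Same-numbered arrays deviated together, with a correlation across probe sets of 0.479 over all probe sets and 0.662 over those with a symbol. With the replicate block, 0 probe sets passed and 5279 stood at an unadjusted p under 0.05. With the replicate block and probe sets naming 1 gene, 9 passed, all 9 lower, and 5176 stood at that p (Ogt -1.54, adjusted p = 0.0607). The 9 were Sycp3, Gm1564, Rnf17, Plac9, Zhx1, 1700001L05Rik, Mgea5, Nxt2 and Ott, named after their values were seen. With a variance trend added, 1844 passed, 1002 higher and 842 lower, with 5885 at an unadjusted p, and Ogt (-1.54) passed with an adjusted p of 0.00316, as did all 20 of the 20 genes named by the smallest p, none of which passes without the block. With the block, at the preset correlation, the 2-cell-like list passed (2.97e-05) and the germline list turned higher (0.962). The block was not run with an estimated correlation or fry, and without it the 2-cell-like list had an adjusted p of 0.787 with an estimated correlation and 0.859 in fry. With the block, 15 of 28 germline members stood at an unadjusted p under 0.05, against 13.4% of all gene symbols.

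The count at an unadjusted p was 1512 among probe sets above the median level, and without 1 array it ranged from 1276 (without control 2) to 2788 (without silenced 1). Members passing over the list alone numbered 6 for the O-GlcNAc list with the replicate block and probe sets naming 1 gene, and 7 with the variance trend added. For the germline list they numbered 9 with probe sets naming 1 gene, 9 without the accession-less probe sets, 12 with the replicate block, 15 with the block and probe sets naming 1 gene and 16 with the trend added, and from 0 (without control 1, control 2 or silenced 2) to 7 (without silenced 1). For cholesterol synthesis they numbered 0 after quantile normalization, 0 with a variance trend, 0 with a robust prior, 5 with the block, 6 with the block and probe sets naming 1 gene and 8 with the trend added, and from 0 (without control 1, control 2 or silenced 2) to 2 (without silenced 1).

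The number of lists passing was 0 with an estimated correlation and 0 in fry, and from 3 (without control 2) to 5 without 1 array. The adjusted p of the interferon, cholesterol, Wnt, Nodal and BMP, ribosomal and histone lists was 0.774 with an estimated correlation. In fry it was 0.629 for interferon, 0.828 for cholesterol, for Wnt, Nodal and BMP and for ribosomal genes, and 0.726 for histones. The Wnt, Nodal and BMP list had 0.0593 after quantile normalization and 0.111 among probe sets above the median level, where the naive list turned lower (0.988). Without 1 array, adjusted p ranged from 0.00816 to 0.234 for interferon, 1.58e-10 to 0.578 for cholesterol, 0.000185 to 0.400 for Wnt, Nodal and BMP, 1.84e-08 to 0.0635 for ribosomal genes and 0.000170 to 0.0749 for histones. The lists that passed without 1 array and not with all were 2-cell-like (4.73e-08 without control 1, up to 0.400, where it turned higher without silenced 1, as without control 2), imprinted (0.0192 without silenced 2, up to 0.975) and ATF4 (0.00690 without silenced 1, up to 0.969). Lists that turned in direction without 1 array, or moved without passing, had ranges of 0.355 to 0.969 (O-GlcNAc), 0.161 to 0.969 (DNA methylation and TET), 0.177 to 0.849 (Polycomb), 0.161 to 0.621 (naive), 0.180 to 0.931 (endoderm), 0.161 to 0.849 (trophectoderm), 0.190 to 0.975 (p53), 0.185 to 0.903 (glycolysis) and 0.137 to 0.975 (G1/S). The log2 change ranged from -0.053 to 0.079 for Tet1, -0.0046 to 0.029 for Pou5f1, -0.047 to 0.16 for Nanog, -0.49 to 0.040 for Spz1 and -1.03 to 0.15 for Sp110.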

Other observations

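The tests of the germline list against random lists of the same level, and of the wider spread of the accession-less probe sets, were chosen after the result was seen, as were the genes of the next paragraph.

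Among the 57 gene symbols at an unadjusted p under 0.05 that differed by 2-fold or more, 43 were lower and 14 higher in the silenced samples, while the 367 at 1.5-fold or more split into 168 lower and 199 higher. The lowest value belonged to Ott, a gene family of the X chromosome, with a log2 change of -2.77 (SE 0.34) at the probe set with the highest mean. Its 7 probe sets disagreed. In 6 of them the change was negative and 4 stood at an unadjusted p under 0.05, but the others ran from -1.57 to 0.49. Further genes lowered by 2-fold or more were Gm1564, now named Meioc, at -2.18 (SE 0.41), Qdpr, which regenerates tetrahydrobiopterin, at -1.53 (SE 0.24), and the phosphatase gene Pdxp at -1.08 (SE 0.31). Syce1, a synaptonemal complex gene, stood at 1.03 (SE 0.31). None of these passes over all genes in the fit with group as the only term. Ott and Gm1564 passed with the replicate block and probe sets naming 1 gene.

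The germline list held 11 of 28 members at an unadjusted p under 0.05. A draw of genes of the same level was argued against, since 0 of 10000 level-matched random lists held as many (median 2, highest 8, permutation p = 1e-04, the smallest they can give). Noisy probe sets remain open, since the members' median residual SD was 0.231 against 0.139 in the random lists, and 8 of 10000 random lists reached it. Probe sets without an accession had a higher median residual SD, 0.283, and 12.6% of them stood at an unadjusted p under 0.05. A wider spread alone is therefore not shown to account for the count. Those are other probe sets, however, and do not settle the question for the list. Splitting the arrays by replicate number gave 1 of 28 members (11.6% of all gene symbols) and the crossed split gave 0 (0.188%). The groups gave 11 of 28, with 6.06% of all gene symbols. Those splits count the group difference as spread, so low counts were likely beforehand for a list picked for its group differences. They cannot serve as controls for the list. A response to the loss of Ogt, the difference the design names, stays open and was not separated from noisy probe sets.

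All 53 ribosomal protein genes were lower, with a median log2 change of -0.16. Their level of expression is argued against, since 0 of 10000 level-matched random lists had a median as low (most extreme -0.07, permutation p = 1e-04, the smallest they can give). The list drifts together between arrays, since 47 of 53 members moved one way when replicate 1 was set against replicate 2, with a median of -0.17. In the crossed split 31 of 53 moved one way, with a median of 0.014, so the fall was similar in both same-numbered pairs. The list moved by as much between arrays of the same groups, and such drift was not separated from an effect of silencing. Both stay open.

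Probe sets without an accession stood at an unadjusted p under 0.05 in 12.6% of cases (827 of 6568), against 6.14% of probe sets with a symbol. A background shift between the groups is argued against as the whole account, since the share was 11.2% after centring each array within classes of level. A wider spread under 1 shared variance prior is consistent with the crossed split, which sets no group against another and gave 6.44% against 0.244%. Their median residual SD was 0.283 against 0.135, and fitted alone they gave 5.21%. Of the 827, 585 were higher and 242 lower, against 769 higher and 665 lower among probe sets with a symbol. A symmetric wider spread alone would not give such a skew. The median log2 change was 0.089 without an accession and -7.9e-05 with a symbol. Directions were not counted after centring, so the skew was not separated from that offset. The design gives no biological explanation that could be tested for the probe sets without an accession.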
